A study of Mus musculus with 4 samples.

How the data were processed

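Total RNA of ICR mouse kidney was amplified, labelled with Cy3 by the Low Input Quick Amp kit and hybridized to Agilent mouse expression arrays, 1 array per sample. The 4 samples were saline at ZT2, vancomycin at ZT2, saline at ZT14 and vancomycin at ZT14, and each was taken 1 day after injection. Images were read by Agilent Feature Extraction, version 10.7.1.1 per the file headers, whereas the submitters' processing notes name version 9.5.1.1. Per the file headers, the processed signal of each array is an intensity from which background was subtracted and spatial and multiplicative trends were removed, with surrogate values near background and no normalization between arrays. The raw mean and local background intensities of each spot were deposited in the same files, with flags for spots well above background, saturated or not uniform. The authors also deposited a table of intensity values by probe, on a linear scale. Its 4 columns had the same median, 35.2, and the same quartiles, so these values were quantile normalized over the 4 arrays, and this table was used only as an alternative. Arrays give no read depth. Their number, 1 per group, limits the precision, and so does the signal over background.

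The share of spots well above background was 62.2%, 60.6%, 64.7% and 62.2% in the order of samples above, and 0 spots were saturated. The 75th percentile of the processed signal was 547.7, 490.8, 678.1 and 651.1. Probes with 10 spots had a median SD of log2 signal between spots of 0.041 to 0.049 within an array, which is technical spread and not spread between animals. The slope of the line fitted to the spike-in controls, per the file headers, was 0.935, 0.877, 1.004 and 1.002.

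Log2 processed signals were centred on each array's 75th percentile. Spots marked as not uniform or as population outliers were left out and replicate spots averaged. A probe was kept if at least 50% of its spots were well above background on at least 1 array. Of 56605 probes, 19099 were above background on 0 arrays and 31383 on all 4. Each gene entry was represented by its brightest probe, which left 24638 genes, of which 20759 were above background on all 4 arrays. Gene names are those of the array files, and 32994 probes were matched by accession and 10224 by symbol to a RefSeq table of the GRCm38.p6 assembly, which was used for names only. Probe coordinates are those of the array files, in mm9 as the headers state, and no genome was used here. Where a probe was well above background on only 1 of 2 arrays, the dim signal was replaced by the lowest signal well above background on that array if it lay under it, and the change is given as a bound ("at least").

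Differences at a single time are vancomycin minus saline in log2 units, with a 2-fold size rule and no test. Over both times, limma fitted treatment and injection time as additive terms, with eBayes and Benjamini-Hochberg adjusted p under 0.05 over all genes. The same fit gave ZT14 minus ZT2. It has 1 residual degree of freedom, which also holds any difference of the effect between times, and the prior added 1.86. The difference of the effects between times leaves no residual degrees of freedom. SE values are moderated, from this fit. There were 31 gene lists with 520 members, of which 495 were measured. They covered tubular injury, nephron segments, podocytes, endothelium, macrophages, neutrophils, lymphocytes, cytokines, interferon, NRF2, p53, endoplasmic reticulum stress, cell death, heat shock, extracellular matrix, cell cycle, oxidative phosphorylation, fatty acid oxidation, cholesterol, lysosome, drug transport, metal handling, complement, the clock, glucocorticoids, immediate early genes, adrenal, adipose and erythroid markers and sex-linked genes. Some genes stand in more than 1 list, such as Pdk4, Lcn2, Mt2, Dusp1, Btg2 and Slc4a1. Of 10 adrenal markers 6 were well above background on both saline arrays, so their signal was not confined to vancomycin. Whether it came from kidney cells was not tested. Lists were tested by fry, which asks whether the genes of a list move on balance in a single direction and, separately, whether they change in either direction, without comparison to other genes. The median of each list was also ranked as a percentile among 10000 random lists of the same size drawn from 20 bins of mean signal, and called outside when under 2.5 or over 97.5. A list's genes are correlated, so these percentiles are not p-values. In medians with dim probes at their bound, genes well above background on neither array count as 0.

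The samples, groups, comparisons, lists, tests, alternatives other than cyclic loess, and the rule for naming genes were set before the data were examined. The rule named, for each comparison, the genes with the largest changes that had an ordinary symbol. Over both times these were 10 each way by the smaller change of the 2 times, since 0 genes passed, at each time 10 each way, for the difference between times 8 each way and for ZT14 minus ZT2 8 each way. It also named up to 4 members per list with the largest mean change, every clock gene, and every tubular injury marker past 2-fold. A few of the genes that the rule named are not given here. Of 203 named genes 73 had more than 1 measured probe, and for 6 another probe had the opposite sign where the used probe had changed 2-fold or more.

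Alternatives, changed singly, were centring on the median, quantile normalization, cyclic loess, normexp background correction with an offset of 50, the authors' table, no filter on dim probes, only probes above background on all 4 arrays, the mean over probes, a pseudocount of 16, the fit without the other factor, an intensity trend with a robust prior, and each array left out in turn. With the other factor as a term, leaving out an array leaves no residual degrees of freedom, so these fits were run without it. The steps were tested on simulated data with 50 genes at each size of change. The simulated spread was drawn from the prior of the fit to these arrays, so a difference of the effect between times counts as spread. At a log2 change of 1, 48% passed the 2-fold size rule at ZT2, at 2 it was 100%, and 5.99% of 24438 unchanged genes passed it too. For limma, 7 of the unchanged genes passed. Programs were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Left out were control spots and 13387 probes without a name match from the name check only.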

Results

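Kidney RNA from mice of the outbred ICR strain was measured on 4 single-colour expression arrays. Mice had received saline or vancomycin, a glycopeptide antibiotic that is known to injure the kidney at high exposure, at zeitgeber time 2 (ZT2) or 14 (ZT14), counted in hours from the start of the light phase. Kidneys were taken 1 day after the injection. Each of the 4 groups had 1 array, so there were no replicates, and differences at a single injection time are values with no test. The labels do not say whether a sample was 1 mouse or a pool of mice. With treatment and injection time in the fit, the p-values measure how far the vancomycin changes at the 2 times differed. This is not a spread between animals. They also rest on a prior spread shared over all genes (SD 0.168). A small SE can thus come from this prior and from 2 changes that match. Each array held 59305 spots for 56605 probes. The number of spots well above background was 36863 for saline at ZT2, 35934 for vancomycin at ZT2, 38398 for saline at ZT14 and 36892 for vancomycin at ZT14. Both ZT2 arrays lay on a single slide and both ZT14 arrays on another, so slide and injection time cannot be told apart. Within each slide saline was at position 1.1 and vancomycin at position 1.2, so position and treatment cannot be told apart either. Pearson's r between arrays across genes, which are not independent replicates, was 0.986 between the ZT2 arrays and 0.990 between the ZT14 arrays, against 0.972 to 0.977 across slides.

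The series compares saline with vancomycin, and over both injection times 4 genes of the circadian clock, the feedback loop that sets daily rhythms, passed limma when adjusted over their list alone. The clock list as a whole did not pass fry for a single direction (adjusted p = 0.25) or for either direction (adjusted p = 0.05 after rounding). By fry in either direction it passed with centring on the median (0.033), quantile normalization (0.048), the authors' values (0.049), a pseudocount (0.027) and cyclic loess (0.047). It did not pass in the other settings (0.063 to 0.11). Transcripts of Dbp and Ciart, which are driven by the clock activators, fell with vancomycin. On the log2 scale Ciart changed by -2.18 ± 0.14 (SE, n = 2 arrays per treatment), a 4.52-fold decrease, and Dbp by -1.88 ± 0.16. Arntl, which encodes the activator BMAL1, and Nfil3, a repressor of Dbp target genes, rose by 1.12 ± 0.14 and 1.37 ± 0.14. The size was alike at the separate times, with Ciart at -2.17 at ZT2 and -2.18 at ZT14, and Arntl at 1.11 and 1.14. Of the 19 measured clock genes, 5 were higher and 9 lower with vancomycin at both times. Among these, Npas2, a partner of BMAL1, was higher by 1.62 at ZT2 and by at least 0.72 at ZT14, and Nr1d1, a repressor of Arntl, differed by -0.69 and -1.42. Core members such as Clock, with 0.36 and -0.05, and Per2, with -0.11 and 0.08, differed little. The median over the list was -0.27 at ZT2, at percentile 0.1 of random lists matched on expression, and -0.07 at ZT14, at percentile 11.1. By limma 4 members passed when adjusted over the list alone (adjusted p = 0.013 for Ciart, 0.016 for Dbp, 0.018 for Nfil3 and 0.021 for Arntl), and 0 passed when adjusted over all genes (adjusted p = 0.52 each). Without injection time as a term in the fit these 4 calls were lost, with adjusted p over the list alone of 0.094 for Ciart and Dbp, 0.16 for Nfil3 and 0.28 for Arntl. In mm9, the build named in the file headers, the probes of Dbp and Arntl lay on chromosome 7 at 52965265 to 52965324 and 120456978 to 120457037, and that of Ciart on chromosome 3 at 95682433 to 95682492.

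Most genes of the heat shock list were also higher with vancomycin at both times, though the list did not pass fry for a single direction (adjusted p = 0.18). The inducible chaperone genes Hspa1a and Hspa1b rose by 2.13 ± 0.14 and 1.70 ± 0.14 (SE, n = 2 arrays per treatment), which is 4.38-fold and 3.24-fold. Other genes of the heat shock list were higher by less, with the co-chaperone gene Dnajb1 at 0.74 at ZT2 and 0.71 at ZT14 and Hsph1 at 0.43 and 0.69. In all, 9 of the 12 measured heat shock genes were higher at both times and 0 were lower at both. By limma Hspa1a and Hspa1b passed when adjusted over the list alone (adjusted p = 0.0083 each) and not over all genes (adjusted p = 0.52). Without injection time as a term this adjusted p was 0.27 for both. The list median was 0.27 at ZT2 and 0.31 at ZT14, at percentile 100 both times. Among 17 genes of the endoplasmic reticulum and integrated stress response the median was 0.21 at ZT2 and 0.18 at ZT14, at percentiles 99.9 and 99.7. Ddit3, a transcription factor of this response, was higher by 1.09 and 1.12, the chaperone cofactor Sdf2l1 by 0.64 and 0.68, while Asns, the asparagine synthetase gene, was lower with -0.68 and -0.70. The Hspa1a and Hspa1b probes lay on chromosome 17 at 35106766 to 35106825 and at 35093374 to 35093405.

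Genes of fatty acid oxidation and targets of the lipid sensor PPAR-alpha were higher in 13 of 21 cases at both times and lower in 3. Angptl4, an inhibitor of lipoprotein lipase, was higher by 0.89 at ZT2 and 1.28 at ZT14, Cyp4a10 by 0.93 and 1.23, and Cyp4a14 by at least 0.68 and by 1.27. The list median was 0.26 at ZT2, at percentile 100, and 0.10 at ZT14, at percentile 95, which lay outside the central range with quantile normalization or the authors' values (percentile 97.9 each) and with the mean over probes (99.6). Oxidative phosphorylation genes differed by a small amount, with a median of 0.08 at ZT2 and 0.11 at ZT14 (percentiles 97.7 and 98.3), inside the central range with normexp background correction and, at ZT2, with the authors' values. The subunit genes Ndufb5, with 0.13 and 0.20, and Cox5a, with 0.21 and 0.12, were among the 11 of 22 that were higher at both times, and 0 were lower at both. In these lists 0 members passed limma when adjusted over the list alone or over all genes.

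Most lymphocyte markers were lower with vancomycin at both times, though the list did not pass fry for a single direction (adjusted p = 0.20). The list had medians of -0.72 at ZT2 and -0.73 at ZT14, at percentiles 0.1 and 0, which became -0.20 and -0.17 with normexp background correction, and 10 of its 11 measured members were lower at both times. Cd79b, a chain of the B cell receptor complex, fell by 1.42 on the log2 scale, with an SE of 0.21 (n = 2 arrays per treatment). The T cell receptor genes Cd3d and Cd3g changed by -0.99 ± 0.14 and -0.80 ± 0.14, and the cytotoxic granule gene Gzma by -0.83 ± 0.15. Cd3g and Gzma were named after their values were seen. By limma 5 members of the list, these 4 among them, passed when adjusted over the list alone (adjusted p = 0.03 each) and 0 passed over all genes (adjusted p = 0.52). Cd3d, Cd3g and Gzma lost the call with normexp background correction, and Cd3g also with a pseudocount and with an intensity trend and robust prior. Without injection time as a term all 5 were lost, and for Cd79b the adjusted p over the list alone was then 0.059. Ms4a1, a B cell gene, was higher by at least 0.58 at ZT2 and not well above background on either ZT14 array.

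Medians of 5 other lists of leukocyte, vessel and inflammation genes were below 0 at both times, and by fry 0 of these lists passed for a single direction. The 15 macrophage and monocyte markers had a median of -0.47 at both times (percentile 0), and 12 were lower at both. The fractalkine receptor gene Cx3cr1 was lower with -0.99 at ZT2 and -0.96 at ZT14, Mrc1 with -0.61 and -0.65, Lyz2 with -0.67 and -0.57, and the chemokine receptor gene Ccr2 with at least -2.34 and with -1.04. The 12 endothelial markers had medians of -0.35 and -0.31, at percentiles 0.1 and 0, and 11 were lower at both times, among them the growth factor receptor gene Kdr, with -0.45 and -0.54. Inflammatory cytokines and NF-kB targets had medians of -0.30 and -0.29 over 18 genes, at percentiles 0.5 and 0.2, and the T cell chemokine gene Ccl5 was lower with -1.50 and -1.86. With dim probes at their bound the ZT2 median was -0.27, and with normexp background correction the medians were -0.14 and -0.13. Interferon response genes had medians of -0.29 and -0.37 over 19 genes, at percentiles 0.1 and 0, which became -0.11 and -0.32 with dim probes at their bound. With normexp background correction they were -0.05, inside the central range of random lists, and -0.22. Irf7, a regulator of interferon genes, was lower with -0.88 and -0.61. Neutrophil markers had medians of -0.20 and -0.09 over 8 genes, inside the central range of random lists but for ZT2 with normexp background correction (percentile 0.7), or 0.11 at ZT14 with no filter on dim probes, with S100a8 at -0.99 and -0.69. In these 5 lists 0 members passed limma when adjusted over the list alone.

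Tgfb2, a growth factor gene of matrix deposition, fell with vancomycin by 3.93 on the log2 scale, with an SE of 0.33 (n = 2 arrays per treatment), a 15.3-fold decrease. It passed limma when adjusted over the extracellular matrix list alone (adjusted p = 0.028) and not over all genes (adjusted p = 0.52). Its probe lay on chromosome 1 at 188449333 to 188449392. Outside the lists, the genes with the largest smaller change of the 2 times included Col4a3, a collagen gene of the glomerular basement membrane, higher 5.66-fold at ZT2 and 4.82-fold at ZT14, and Hao2, a peroxisomal oxidase gene, higher by 1.78 and 1.48 on the log2 scale. Ctcfl, Arhgef19, Rrp8 and Lgalsl followed with 1.16 to 1.71. Npy, which encodes neuropeptide Y, was lower with -3.53 and -4.54, the synaptic vesicle gene Synpr with -6.95 and -3.27, and the ciliary gene Tekt1 with -2.81 and -4.00. Ces1g, a carboxylesterase gene, had -3.53 and -2.64, the organic anion transporter gene Slco1b2 -2.55 and -3.07, Slc37a1 -2.29 and -2.22, Il18bp, a decoy for interleukin 18, -2.32 and -1.95, and Klhl6 -3.31 and -1.84. The Npy probe spanned 49773743 to 49777505 on chromosome 6 and that of Col4a3 82714546 to 82715399 on chromosome 1.

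Among 20759 genes well above background on all 4 arrays, 37 were higher by 2-fold or more at both times, against 3.0 if the times were independent, and 176 were lower at both, against 13.8. These genes include 87 immunoglobulin entries, a set chosen after the data were seen. Of 183 such entries measured, 164 were lower at both times. Their probes share similar sequences, so the 176 are not independent genes. How many of the 176 are such entries was not counted. The counts for independent times treat all genes as equally likely to pass 2-fold. Opposite 2-fold changes also exceeded theirs, with 21 against 6.1 and 25 against 6.8. An excess over these counts thus need not come from a shared change. The log2 changes at the 2 times had a Pearson's r of 0.265 and a Spearman's rho of 0.222 across genes. By limma with injection time as a term, 0 of 24638 genes passed an adjusted p of 0.05 for vancomycin, and the smallest adjusted p was 0.52. At an unadjusted p under 0.05 there were 790 higher and 1317 lower genes, against 1232 in all that chance would give. The count was also 0 without the injection-time term and with an intensity trend and robust prior. The fit had 1 residual degree of freedom. In a simulation of this design, with the spread of this fit, 0% of genes with a log2 change of 2 passed, 46% with 4 and 76% with 6. By fry, which tests each list on its own, 0 of 31 lists moved on balance in a single direction at an adjusted p of 0.05 (smallest 0.18, for macrophage and monocyte markers and for heat shock), and 6 lists were at an unadjusted p under 0.05. The test for change in either direction passed for 4 lists, with adjusted p of 0.031 for cytokines and NF-kB targets and for heat shock, and 0.039 for lysosome and autophagy and for complement and acute phase. All 4 of these calls were lost with normexp background correction (adjusted p from 0.063 to 0.12) and with only probes well above background on all 4 arrays (0.07 to 0.15). The call for cytokines was also lost with no filter on dim probes (0.98), that for lysosome with the mean over probes (0.11) and a pseudocount (0.062), and that for complement in every other setting but centring on the median and cyclic loess (0.08 to 0.11).

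**Figure D1:**
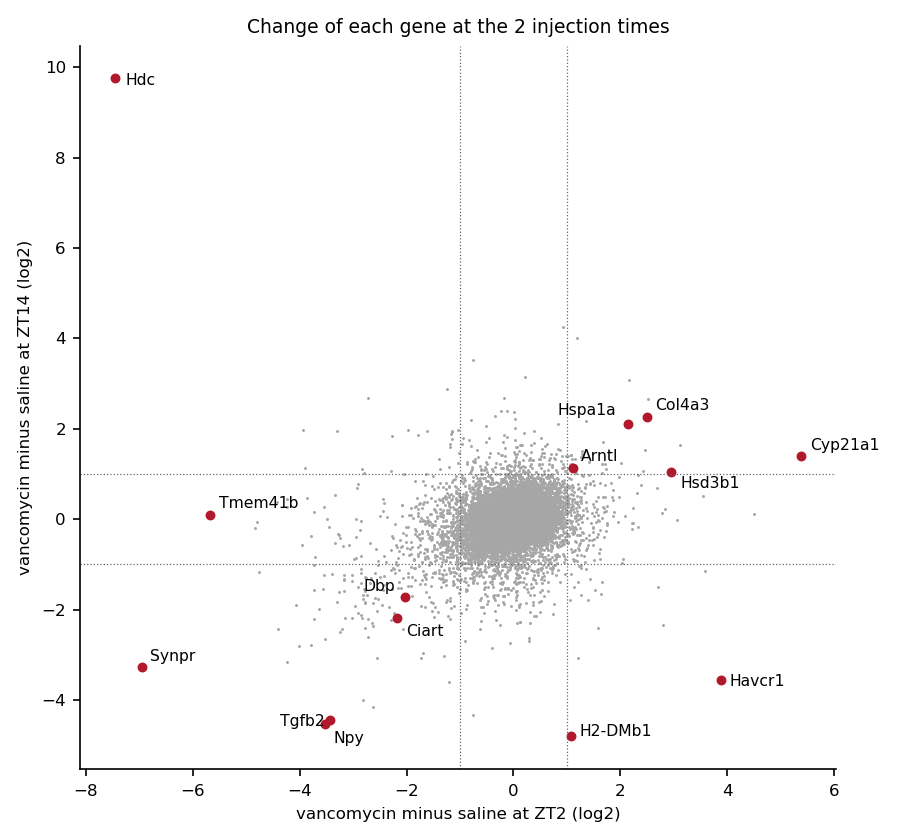
Each point is a gene well above background on all 4 arrays, with its log2 change from saline to vancomycin at ZT2 on the horizontal axis and at ZT14 on the vertical axis; dotted lines mark 2-fold changes. Hspa1a and Col4a3 lie high on both axes, Tgfb2, Npy and Synpr low on both, and Hdc and Havcr1 at opposite ends.

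**Figure D2:**
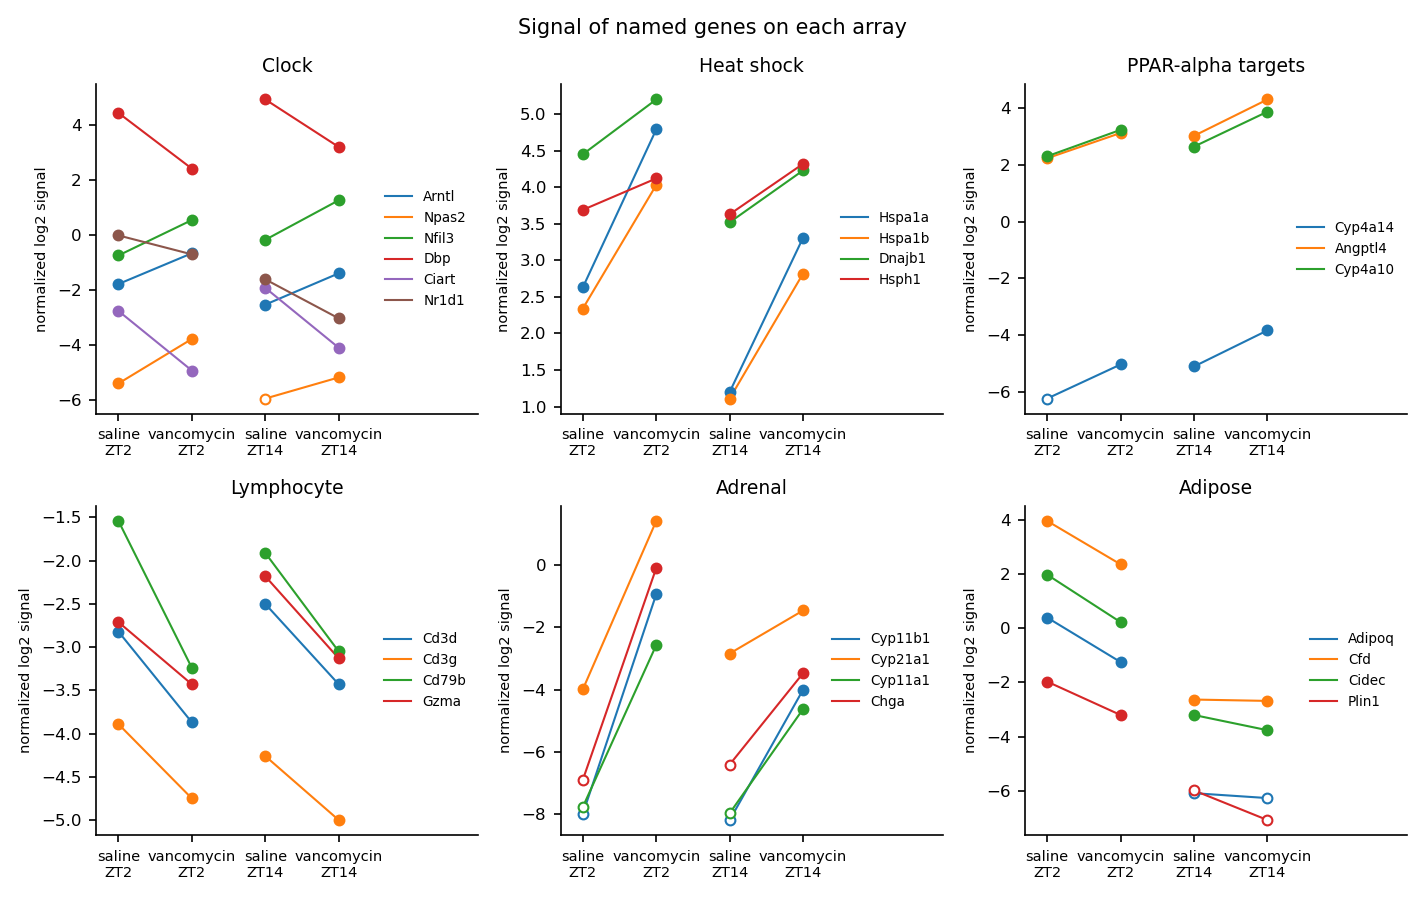
Normalized log2 signal of named genes on each of the 4 arrays, with a line joining saline and vancomycin at each injection time and open circles for probes not well above background. Hspa1a was higher by 2.15 at ZT2 and 2.11 at ZT14, and Cd79b differed by -1.70 and -1.14.

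At ZT2 the kidney from vancomycin showed high signals of adrenal genes. Cyp21a1, an enzyme gene of corticosteroid synthesis, was higher by 5.39 on the log2 scale, or 42.1-fold, Hsd3b1, another steroid enzyme gene, by 2.94, Cyp11b1 by at least 4.77, Cyp11a1 by at least 3.14 and Chga, a secretory granule gene of the adrenal medulla, by at least 5.61. The 10 measured adrenal markers had a median of 2.81, at percentile 100, or 1.63 with normexp background correction, and 6 were higher by 2-fold or more. Another, dimmer probe had the opposite sign for Cyp21a1 at ZT2 and for Cyp11a1 at ZT14. The Cyp21a1 probe lay on chromosome 17 at 34938298 to 34938357 and that of Cyp11b1 on chromosome 15 at 74665330 to 74665389. Among genes with an ordinary symbol, the largest measured increase was that of Azgp1, a secreted glycoprotein gene of lipid mobilisation, with 8.06. Havcr1, the kidney injury molecule gene of damaged proximal tubules, was higher by 3.89, or 14.8-fold, and the efflux pump gene Abcb1b by 2.83. Cdk14, Adgrg4, Dlk1, Mgarp and the erythroid regulator gene Klf1 were higher by 2.78 to 3.59.

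Several tissue markers were lower at ZT2. The 18 extracellular matrix genes had a median of -0.93 (percentile 0), with Col1a1 at -1.83, Col1a2 at -1.23 and the smooth muscle actin gene Acta2 at -1.79, and 8 were lower by 2-fold or more. Erythroid markers had a median of -1.97 over 8 genes (percentile 0), or -1.22 with normexp background correction, with the haemoglobin gene Hba-a1 at -2.09 and the haem synthesis gene Alas2 at -2.45. Adipose markers had a median of -1.42 over 12 genes (percentile 0), with the lipid droplet gene Cidec at -1.74. By 2-fold or more, 7 were lower and 2 higher. Cidea was higher by 1.58, and the thermogenic gene Ucp1 was above background only with vancomycin. Cell cycle genes had a median of -0.83 over 20 genes (percentile 0), or -0.64 with dim probes at their bound and -0.22 with normexp background correction, and the mitotic genes Cdc20 and Birc5 had -1.27 and -0.99. Complement and acute phase genes had a median of -0.84 over 16 genes (percentile 0), or -0.50 with dim probes at their bound and -0.31 with normexp background correction, and the haptoglobin gene Hp had -1.53. Of 26 tubular injury markers, whose median was -0.35 (percentile 0), or -0.20 with only probes well above background on all 4 arrays, Havcr1, Gdf15 and Atf3 were higher by 2-fold or more, the last pair with 1.48 and 1.11. The 4 others past 2-fold were lower, the urokinase receptor gene Plaur with -1.53, Sprr2f with -1.27, Cd44 with at least -1.45 and Fgb with at least -2.10. By the naming rule, which passes over entries without an ordinary symbol, the largest decrease was that of Hdc, which makes histamine, with -7.46. It was followed by Synpr, Tmem41b with -5.67, Lhfpl1 with -4.84 and the antigen presentation gene H2-Eb1 with -4.24. Some immunoglobulin entries passed over were lower than H2-Eb1, such as a lambda constant entry with -4.76. Naaladl2, Wnt10a, Cyp2b9 and the immunoglobulin light chain gene Iglv1 differed by -3.55 to -3.90. Among 23082 genes compared at ZT2, 453 were higher and 886 lower by 2-fold or more, of which 156 and 227 were known only as a bound. With only probes well above background on all 4 arrays there were 276 higher genes. With no filter on dim probes the balance turned, with 2385 higher and 2072 lower. In simulated data, with all probes counted as above background, 1465 of 24438 unchanged genes (5.99%) also passed the 2-fold rule at ZT2. The simulated spread came from the fit to these arrays, where any difference of the effect between times counts as spread. This share is therefore no independent rate of false calls. The observed counts alone neither show nor exclude a change with vancomycin.

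At ZT14 6 of the 10 adrenal markers were higher by 2-fold or more, though not the same 6 as at ZT2. Star, named after its values were seen, had 2.68 at ZT2 and 0.68 at ZT14. Dbh was higher by at least 0.73 and at least 1.02. Nr5a1, Fdx1 and Th differed at ZT14 by 0.00, -0.01 and -0.06. Over both times the list did not pass fry for a single direction (adjusted p = 0.38) or for either (adjusted p = 0.21). Their median was 1.22 (percentile 100), or 1.04 with dim probes at their bound, 0.50 with normexp background correction and 0.34 with only probes well above background on all 4 arrays, with Cyp21a1 higher by 1.39, Cyp11b1 by at least 1.91, Cyp11a1 by at least 1.29 and Chga by at least 2.44. Over both times limma gave 4.26 ± 0.56 for Cyp11a1, 5.61 ± 0.86 for Cyp11b1 and 1.54 ± 0.16 for Dbh (SE, n = 2 arrays per treatment). These fitted values rest on saline signals not well above background. By limma the 3 genes passed when adjusted over the list alone (adjusted p = 0.028 each) and not over all genes (adjusted p = 0.52). Without injection time as a term, leaving out the saline array of ZT2 or of ZT14 ended the call for Cyp11b1, with adjusted p over the list alone of 0.094 and 0.07. Dbh, an enzyme gene of noradrenaline synthesis, was named after its value was seen and lost the call with normexp background correction and with an intensity trend and robust prior. Among genes with an ordinary symbol, the largest increase at ZT14 was that of Hdc, with 9.75, whose probe lay on chromosome 2 at 126419516 to 126419575. It was followed by the lysozyme-like gene Lyzl6 with 4.65, the RNA-binding protein gene Igf2bp1 with 4.24, Atoh7 with 3.51 and the lectin gene Itln1 with 3.15. Hesx1, Gfra1, Il1rl2 and Mansc4 were higher by 2.22 to 2.67.

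Among the lowest genes at ZT14 were H2-DMb1, a gene of antigen loading, with -4.80, the water channel gene Aqp8 with -3.61, Chrm1, a muscarinic receptor gene, with -3.28, and the lymphotoxin gene Lta with -3.08, beside Npy, Tgfb2, Tekt1, Synpr and Slco1b2. Havcr1 was lower with -3.56, and its probe lay on chromosome 11 at 46592056 to 46592115. Its normalized log2 signal at ZT14 was -1.11 with saline and -4.68 with vancomycin, against -4.27 and -0.38 at ZT2. The saline signal of Havcr1 was thus itself higher at ZT14 than at ZT2. Tubular injury markers had a median of 0.02 at ZT14 (percentile 56), or 0.00 with dim probes at their bound, and Sprr2f, with at least -3.47, was the other member lower by 2-fold or more. Cell cycle genes had a median of 0.63 (percentile 100), with Rrm2 at 0.97 and Cdc20 at 0.49. Erythroid markers had a median of 0.23 (percentile 99.1) and adipose markers 0.19 (percentile 96.7), or 0.07 with dim probes at their bound. The tubular injury, cell cycle, erythroid, adipose and complement lists had 0 members past limma for vancomycin when adjusted over the list alone. The extracellular matrix list had a median of -0.27 (percentile 0) with Tgfb2 as the only member lower by 2-fold or more. Complement and acute phase genes had a median of -0.25 (percentile 0.8), or -0.05 with dim probes at their bound and -0.14, inside the central range, with the mean over probes, and Hp had -2.04. Among 23975 genes compared at ZT14, 384 were higher and 681 lower by 2-fold or more, of which 114 and 160 were known only as a bound. With only probes well above background on all 4 arrays there were 228 higher genes. The share of unchanged genes past the 2-fold rule was not simulated at ZT14. At both times vancomycin gave 20 and 17 of the 31 lists a median outside the central 95% of random lists, and 11 lists lay outside on the same side.

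Nephron and metabolic lists differed by small amounts. Proximal tubule genes had medians of 0.12 at ZT2 (percentile 100) and -0.11 at ZT14 (percentile 0.1) over 28 genes, with the glucose release gene G6pc at 1.74 and -0.27 and the organic anion carrier gene Slc22a8 at 1.41 and -0.35. Their median over both times was 0.01 and their mean -0.01. Genes of the loop, distal tubule and collecting duct had medians of 0.03 and 0.07 over 22 genes, with the proton pump gene Atp6v1b1 at 0.04 and -1.59 and the renin gene Ren1 at -1.14 and -0.29. Podocyte markers had medians of -0.06 and 0.29 over 10 genes (percentiles 28.8 and 99.9), the latter inside the central range with the mean over probes, with Cdkn1c at 0.36 and 0.72 and the slit diaphragm gene Nphs1 at 0.09 and -0.60. Cholesterol synthesis genes had medians of -0.06 and 0.21 over 16 genes (percentiles 16.4 and 100), with Insig1, a regulator of sterol sensing, at 0.45 and 0.90. Lysosome and autophagy genes had medians of -0.03 and -0.25 over 20 genes (percentiles 30.8 and 0), or -0.21 at ZT14 with dim probes at their bound, with the lysosomal cholesterol carrier gene Npc2 at -1.27 and -0.91 and the protease gene Ctss at -0.61 and -0.76.

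The NRF2 list had medians of 0.14 and 0.03 over 18 genes (percentiles 99.4 and 55.9), the former inside the central range with quantile normalization, the authors' values or the mean over probes, with Osgin1 at 0.75 and 0.88 and the redox enzyme gene Srxn1 at -0.71 and -0.58. Glucocorticoid response genes had medians of 0.19 and -0.01 over 13 genes (percentiles 99.1 and 37.3), with Pdk4, a switch from glucose to fat use, at 0.57 and 1.47 and Fkbp5 at -0.38 and -0.22. Inside the central range at both times were the p53 targets, with medians of 0.02 and 0.00 over 16 genes and Plk2 at -1.08 and -0.48, and the cell death genes, with -0.13 and -0.12 over 18 genes and the inflammatory caspase gene Casp1 at -0.46 and -1.25. The cell death list lay outside at ZT2 with the mean over probes (median -0.30, and -0.03 at ZT14) and at ZT14 with normexp background correction (percentile 1.1). The p53 targets had a mean over both times of -0.08. Immediate early genes also lay inside that range at both times, with 0.10 and 0.08 over 14 genes, Jun at 0.66 and 0.78 and Fos at -0.79 and 1.61. So did genes of drug transport and metabolism, with 0.04 and 0.00 over 22 genes and the oxidase gene Fmo5 at -0.36 and -1.74, though another probe of Fmo5 had the opposite sign at ZT14. Metallothionein and metal handling genes had -0.11 and 0.04 over 10 genes, with Mt1 at 0.47 and 0.56. The 4 measured sex-linked genes had 0.03 and 0.12, with Uty at 0.30 and 0.13. In these lists and those of the nephron, cholesterol and lysosome 0 members passed limma when adjusted over the list alone. The sign of the median turned with at least 1 alternative processing at ZT2 for lysosome, metallothionein, immediate early and sex-linked genes, and at ZT14 for neutrophil, p53, drug transport and glucocorticoid genes.

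**Figure D3:**
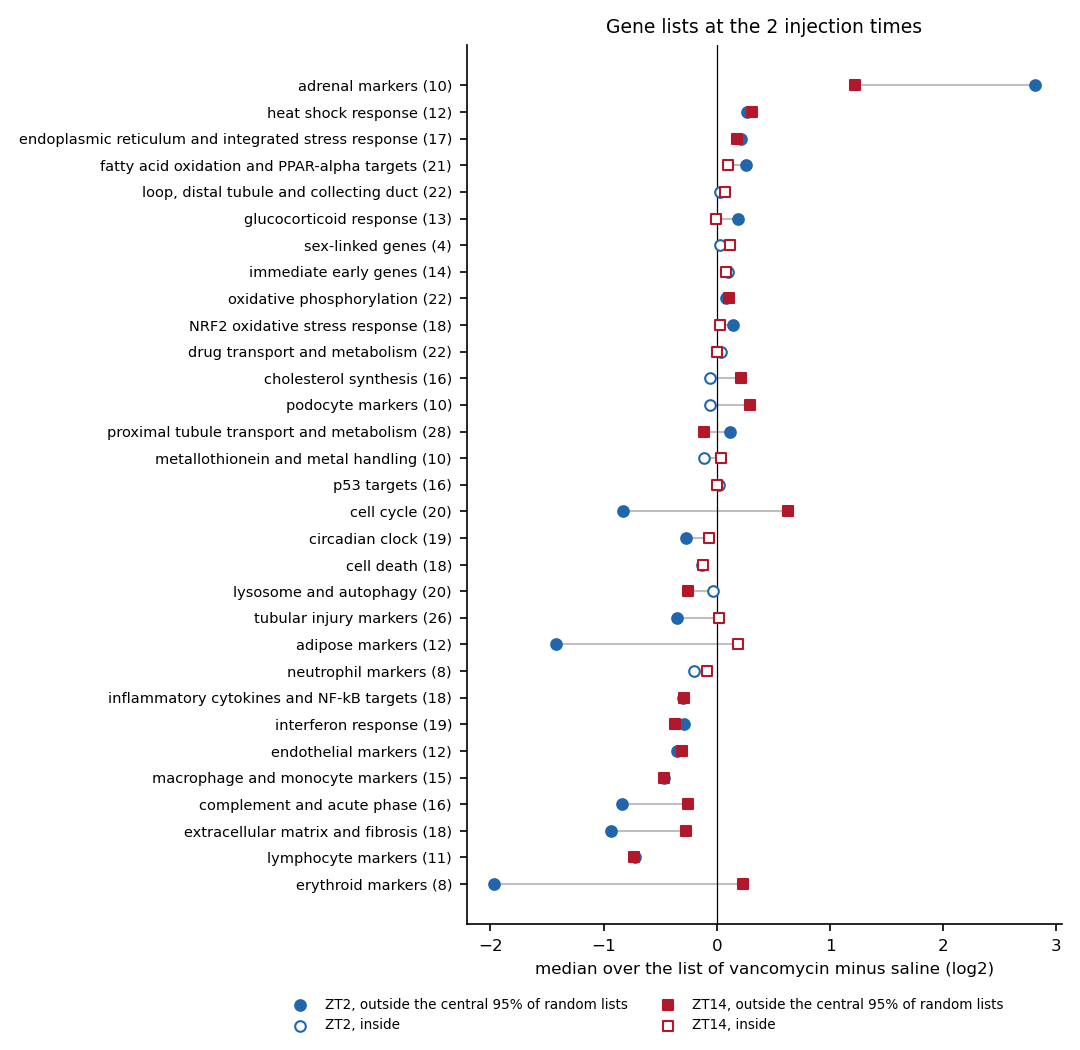
Median log2 change from saline to vancomycin of each gene list (number of measured genes in brackets) at ZT2 (circles) and ZT14 (squares), filled where the median lay outside the central 95% of 10000 random lists matched on expression. Adrenal markers lie furthest to the right with 2.81 and 1.22, and the erythroid list spans -1.97 to 0.23.

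The effect of vancomycin at ZT14 minus that at ZT2 shows where the injection times differed, as values with no test, since no degrees of freedom were left. The widest difference among genes with an ordinary symbol was that of Hdc, with 17.22, which was lower with vancomycin at ZT2 and higher at ZT14. Its normalized log2 signal was 2.62 with saline and -4.84 with vancomycin at ZT2, and -4.69 and 5.07 at ZT14. The saline arrays thus differed as well. Toward higher at ZT14 came Tmem41b, the splicing factor gene Cwc22, with -3.31 and 1.94 at the 2 times, Naaladl2, H2-Eb1, Lhfpl1, Atoh7 and Cyp2b9. Toward higher at ZT2 came Havcr1 with -7.45, H2-DMb1 with -5.88, Cdk14 with -4.72, the lipid kinase gene Pik3c2g with -4.27, Adm2, a vasodilator peptide gene, with -4.20, Rnf39 with -4.01, Cyp21a1 and the sodium pump gene Atp1a4 with -3.30. Another measured probe had the opposite sign for Cdk14 at ZT14 and for Naaladl2 at ZT2. In gene lists, the median difference was 2.01 for erythroid markers, 1.42 for the cell cycle, 0.66 for extracellular matrix and -1.87 for adrenal markers. Among 20759 genes well above background on all 4 arrays, the difference was 2-fold or more toward higher at ZT14 for 673 and toward higher at ZT2 for 571. Opposite changes of 2-fold or more were seen for 21 genes higher at ZT2 and lower at ZT14, against 6.1 if independent, and for 25 the other way, against 6.8. The counts if independent treat all genes as equally likely to pass 2-fold.

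Between ZT14 and ZT2, over both treatments, adipose markers differed most. Cfd, a complement protease gene of fat cells, fell by 5.80 on the log2 scale at ZT14, with an SE of 0.48 (n = 2 arrays per time), the hormone gene Adipoq by 5.74, with an SE of 0.45, and the lipid droplet genes Cidec, Plin1 and Cidea changed by -4.58, -3.94 and -3.82. Adipoq and Plin1 were not well above background on either ZT14 array, so their fitted sizes rest on signals at background. These 5 of 12 members passed limma when adjusted over the list alone (adjusted p = 0.0046 for Cfd, Adipoq and Cidec, 0.0018 for Plin1 and 0.0049 for Cidea). The list median was -3.88, at percentile 0. The labels do not say whether fat around the kidney was removed, so these values hold for the samples as taken.

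Of 19 clock genes 10 passed limma for time when adjusted over the list alone, with adjusted p from 0.033 to 0.042. Among them Cry1, Wee1, Usp2, Ciart, Per2, Cry2 and Nfil3 rose at ZT14, with Cry1, a repressor of the clock, at 1.49 ± 0.16 and the cell cycle kinase gene Wee1 at 1.18 ± 0.16 (SE, n = 2 arrays per time). Nr1d1 changed by -1.96 ± 0.25 and Arntl by -0.74 ± 0.14. Members that did not pass had ZT14 minus ZT2 values, in saline and then in vancomycin, of 0.49 and 0.79 for Dbp, 0.21 and 0.55 for Per1, 0.22 and 0.90 for Per3, 0.72 and 0.48 for Nr1d2, 0.37 and 0.35 for Tef, 0.59 and 0.28 for Hlf, 0.22 and 0.18 for Bhlhe40 and -0.08 and -0.48 for Clock. Npas2 had -1.40 in vancomycin and was not well above background in saline at ZT14. The calls for Arntl, Nr1d1, Ciart and Nfil3 ended without treatment as a term, with limma adjusted p over the list alone of 0.36, 0.09, 0.53 and 0.49. Those for Ciart, Nfil3, Per2, Cry2 and Usp2 ended with the mean over all measured probes. Without treatment as a term the direction turned for Ciart without vancomycin at ZT2 or saline at ZT14 (adjusted p of 0.84 and 0.85) and for Nfil3 without saline at ZT2 or vancomycin at ZT14 (adjusted p of 1 and 0.95).

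In the heat shock list 6 of 12 genes passed for time when adjusted over the list alone. Hspa1a, Hspa1b, Dnajb1, Hspb1 and Bag3 fell at ZT14, with Hspa1a at -1.45 ± 0.14 and Hspa1b at -1.22 ± 0.14 (SE, n = 2 arrays per time), and Hspa8 rose by 0.82 ± 0.14. By limma the adjusted p over the list alone was 0.021 for Hspa1a and Hspa1b. Without treatment as a term all 6 calls were lost, with adjusted p over the list alone of 0.40 for Hspa1a and Hspa1b and 0.24 for Dnajb1. Those for Hspa8, Hspb1 and Bag3 were also lost with the mean over all measured probes. The acute phase genes Orm1 and Hp changed by -3.39 ± 0.37 and -2.35 ± 0.20 (limma adjusted p = 0.027 for both), and the fibrinogen gene Fgg by -2.16 ± 0.14 (limma adjusted p = 0.019). Orm1 was not well above background on either ZT14 array, and the call for Hp was lost without treatment as a term (adjusted p = 0.36 over the list alone). Among other list members past the same test were the nitric oxide synthase gene Nos2 with 2.21 ± 0.17, Ifi44 with 1.77 ± 0.15, the T helper cell gene Cd4 with 1.68 ± 0.14, the sterol regulator gene Srebf2 with 1.54 ± 0.14, Plin2 with 1.49 ± 0.17 and the neutrophil elastase gene Elane with 1.31 ± 0.14. Calls were lost for Ifi44 and Srebf2 with the mean over all measured probes, and for Plin2 with quantile normalization, the authors' values, cyclic loess and no filter on dim probes. The chemokine genes Ccl3 and Ccl5 also passed, with 1.01 ± 0.14 and 0.88 ± 0.17, but their direction turned, for Ccl3 with a normexp background correction (adjusted p = 0.70) and for Ccl5 without saline at ZT14 (adjusted p = 0.96). Ccl3 was not well above background on either ZT2 array. Of the alternatives with no array left out, 5 of 10 kept the call for Ccl3 and 4 of 11 that for Ccl5. Kdm5d, a Y-linked histone demethylase gene, had -0.84 ± 0.14 and turned with the mean over probes (adjusted p = 0.21). Orm1, Nos2, Ifi44, Cd4, Srebf2, Plin2, Elane, Ccl3, Hspb1, Bag3 and Hspa8 were named after their values were seen. In all, 37 list members passed for time when adjusted over the list alone and 0 when adjusted over all genes.

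By the naming rule, the genes highest at ZT14 in both treatments were the melanin synthesis gene Dct with 4.12 in saline and 4.40 in vancomycin, Erich6 with 3.85 and 3.75, Iqsec3, the olfactory receptor gene Olfr1153, Il22ra1, a receptor chain for interleukin 22, Vmn1r46, Vax2 and Grin2d. Beside the adipose genes, the lowest were the histidine breakdown gene Ftcd with -3.30 and -3.06, the melanocortin receptor partner gene Mrap with -3.08 and -2.80, Tmprss11b and Sntg2. Among 20759 genes, 1002 were higher at ZT14 by 2-fold or more in both treatments, against 121.4 if independent, and 188 were lower in both, against 15.9. The counts if independent again treat all genes as equally likely to pass 2-fold. By limma 0 of 24638 genes passed an adjusted p of 0.05, with a smallest adjusted p of 0.087, while 4426 were higher and 2284 lower at an unadjusted p under 0.05. The count was 3396 with an intensity trend and robust prior and 1332 without treatment as a term. By fry 0 lists moved on balance in a single direction (smallest adjusted p = 0.19), 7 lists were at an unadjusted p under 0.05, and the p53 targets passed for change in either direction (adjusted p = 0.0037, median -0.16). This call was lost with the mean over probes (adjusted p = 0.10) and with a pseudocount (adjusted p = 0.056). Slide and injection time cannot be told apart in any of these values.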

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

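All tests in this part were chosen after the results were seen. In 10 of the named genes the change with vancomycin was 2-fold or more in opposite directions at the injection times, a difference between groups that was not tested, since each group had 1 array. The difference, ZT14 minus ZT2 on the log2 scale, was 17.22 for Hdc, 5.26 for Cwc22 and 5.04 for Naaladl2, which were lower with vancomycin at ZT2 and higher at ZT14. It was -7.45 for Havcr1, -5.88 for H2-DMb1, -4.72 for Cdk14, -4.27 for Pik3c2g, -4.20 for Adm2, -4.01 for Rnf39 and -3.30 for Atp1a4, which were higher at ZT2 and lower at ZT14. Saline signals at ZT2 and ZT14 were 2.62 and -4.69 for Hdc and -4.27 and -1.11 for Havcr1. The opposite changes of Hdc and Havcr1 thus rest in part on the saline samples. In 3 gene lists the medians lay outside the central range of random lists on opposite sides at the 2 times, which was not tested either. The median difference was 2.01 for erythroid markers, 1.42 for cell cycle genes and -0.16 for proximal tubule genes.

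Opposite changes of 2-fold or more were seen for 46 genes in all. Intensity-dependent differences between arrays are argued against as the cause, since 46 of 46 kept opposite 2-fold changes after cyclic loess. Sequence variants under a single probe, which could differ between outbred mice, are argued against as the whole cause in the 11 genes with another measured probe, where 70% of 20 other probes had the same signs, among them all those of Hdc, Cwc22 and Pik3c2g. They stay open for Cdk14, Elmo1 and Naaladl2, of which 0 other probes followed, and cannot be told apart from other causes in the 35 genes with 1 measured probe, Havcr1 among them. Differences between single animals and an effect of injection time on the response to vancomycin also stay open, as untested.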

How the results depend on the processing

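Cyclic loess and its values were chosen after seeing the data; all other alternatives were set before. The count of genes past limma for vancomycin was 0 under every alternative run, and leaving out each array gave 0 to 0 for vancomycin and for time. Changes of named genes past 2-fold reversed in 0 cases. They dropped under 2-fold in 42 values at ZT2, 43 at ZT14 and 17 of the difference, and stayed past it in 752, 604 and 550. Unless construction is named, the cause was not tested. With normexp and an offset of 50, which compresses dim signals by construction, 131 genes were higher and 332 lower at ZT2, 110 and 254 at ZT14, and 18 and 82 at both times. The difference between times was then 2-fold for 280 genes toward ZT14 and 266 toward ZT2, 3008 genes passed limma for time, and by fry for vancomycin 0 lists passed in either direction, while for time 1 passed in a single direction and 7 in either. With no filter on dim probes, which adds genes by construction, 2385 genes were higher and 2072 lower at ZT2, 1449 and 1715 at ZT14, 256 and 469 at both, and 2735 and 3134 differed toward ZT14 and ZT2. That setting moved the median of all genes by 0.11 at ZT2 and made higher genes 53.5% of those past 2-fold, against 33.8%. By fry it gave 1 list in a single direction and 2 in either for vancomycin, and 1 and 4 for time. With only probes well above background on all 4 arrays, fewer genes were tested, 276 genes were higher at ZT2 and 228 at ZT14, 1636 passed limma for time, and by fry in either direction 0 lists passed for vancomycin and 8 for time. With the mean over probes 715 genes were higher at ZT2, and by fry 1 list passed in a single direction for vancomycin and 0 in either direction for time. With a pseudocount of 16, which shrinks dim changes by construction, 209 genes were higher and 540 lower at ZT2, 180 and 448 at ZT14, 446 differed toward ZT14, 1767 passed for time, and by fry 1 list passed in a single direction for vancomycin and 0 in either for time. The 1 list in a single direction for vancomycin was that of lymphocyte markers, lower, in all 3 settings. In either direction by fry, centring on the median gave 8 lists for vancomycin and 6 for time, cyclic loess 7 and 5, and quantile normalization and the authors' values gave 2 each for time. Genes past limma for time numbered 1332 without treatment as a term and 3396 with an intensity trend and robust prior. Adjusted over the list alone, 3 of 15 calls for vancomycin, those of Tgfb2, Cyp11a1 and Cyp11b1, and 13 of 37 for time were kept in every alternative that tested them, arrays left out apart. For time, direction turned for Ccl3 with normexp (adjusted p = 0.70) and for Kdm5d with the mean over probes (adjusted p = 0.21). Leaving out each array gave limma adjusted p over the list alone for time of 0.28 to 0.96 for Ccl5, turned without saline at ZT14, 0.37 to 1 for Nfil3, turned without saline at ZT2 (1) or vancomycin at ZT14 (0.95), and 0.21 to 0.85 for Ciart, turned without vancomycin at ZT2 (0.84) or saline at ZT14 (0.85). For vancomycin these ranges were 0.086 to 0.25 for Ciart and Dbp, 0.17 to 0.95 for Hspa1a and 0.011 to 0.037 for Tgfb2. Signal over background limits the sizes of changes known only as bounds.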

Other observations

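All tests in this part, and the choice of the immunoglobulin entries, came after the data were seen. Immunoglobulin transcripts, the products of B cells and plasma cells, were lower with vancomycin. Of 183 measured entries for heavy, kappa and lambda chains, 164 (89.6%) were lower at both injection times and 1 was higher at both. Their median change was -2.78 on the log2 scale at ZT2 and -1.39 at ZT14, at percentile 0 of random lists each time, and 112 entries were lower by 2-fold or more at both times. With dim probes at their bound the medians were -2.35 and -1.19 and this count was 89, and 87 entries were well above background on all 4 arrays. These probes share similar sequences, so the entries are not independent, and each time rests on 1 array per group.

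Clock genes differed between vancomycin and saline at both injection times, with 11 of 13 genes of the opposed arms on the side of their arm at both. A fault of 1 probe or spot per gene is argued against, since 100% of 5 other probes of Arntl, Dbp, Nfil3 and Ciart had the same signs. An exchange of labels across the injection times stays open. Undoing one of vancomycin ZT2 with saline ZT14 would put Arntl minus Dbp between ZT14 and ZT2 at 3 on the log2 scale, and undoing one of saline ZT2 with vancomycin ZT14 at -3, against -1.38 with the labels as given. Both 3 and -3 restate the change with vancomycin and decide nothing. Kidneys taken at different phases of the clock in the 2 treatments are a candidate explanation, with a gap between the medians of the arms of 1.70 at ZT2 and 1.29 at ZT14. By their used probes Clock and Per2 did not keep to their side. Other Clock probes did, with 0.39 and 0.94, and with 0.14 and 0.34, and another Per2 probe did not, with -0.65 and 0.32. An effect of vancomycin on the clock and differences between single animals cannot be told apart from a difference in phase, since hour of dissection is not in the labels and each group had 1 array.

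Adrenal genes were higher on the vancomycin arrays, above all at ZT2. Adrenal tissue carried over with the kidney and steroid enzyme genes raised in kidney cells are candidate explanations, and neither is excluded here. Carry-over would lower the markers from ZT2 to ZT14 by about 1 ratio. With vancomycin 6 of 10 were lower at ZT14 by 2-fold or more, Cyp21a1 among them, but this restates the pattern, and the changes, from -1.77 to -3.37, spread over 1.60 on the log2 scale. Star, Cyp21a1 and Hsd3b1 were also well above background with saline. That signal was not subtracted, so the spread decides nothing about 1 ratio. Fdx1 and Nr5a1 differed from saline at ZT2 by -0.03 and 0.31. The saline signal of Fdx1 at ZT2 was 4.95, against -1.62 or less for the other markers, so Fdx1 could hardly show a small addition. Why Nr5a1 did not follow was not tested. Steroid enzyme genes raised in kidney cells would leave markers of the adrenal medulla in place. Of 3 such markers 1 was higher by 2-fold or more at ZT2, Chga by at least 5.61, and 2 were at ZT14, Chga by at least 2.44 and Dbh by at least 1.02, while Th differed by 0.78 and -0.06. Chga and Dbh go against that explanation and Th does not, so it stays open. The labels hold no record of the dissection.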
